A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

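Total RNA from budding yeast, Saccharomyces cerevisiae, was measured by strand-specific RNA sequencing in 12 libraries, 2 biological replicates in each of 6 groups. The groups are wild type, wild type with FU and the rrp6 deletion mutant, each at 40 min and 100 min after synchronization. FU is read as 5-fluorouracil from the title of the series. Per the labels, RNA was extracted with hot phenol and depleted of rRNA, and paired-end reads of 2x50 nt came from an Illumina HiSeq sequencer. The dose of FU, its time of addition and the method of synchronization are not given in the sources used here.

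The authors deposited 1 table with a signal per feature and library, a read density: the reads of a feature divided by its length and multiplied by 1 factor per library. TopHat is named for the processing, without a version. This unit was checked on the values. Density times length, divided by the factor of the library, gave whole numbers for 100% of the values at a tolerance of 0.001. The factors set the reads over protein-coding genes of every library to 14370740, the total of wild type at 40 min, replicate 2. The reads of each feature recovered in this way give the depth of each library, 20102931 to 27498217 reads over all features. For genes replicate spread, not counting error, limits values, but tRNAs and MUTs hold few reads. The table holds 12026 features, of which 5798 are genes. Start and end equal those of the R64 reference for 5757 of 5789 genes matched by locus tag. The table itself names no build. The other classes are CUTs (cryptic unstable transcripts), SUTs (stable unannotated transcripts), XUTs (transcripts sensitive to the exonuclease Xrn1), MUTs (meiotic unannotated transcripts), mSUTs (as named in the table), dubious open reading frames, and snoRNAs, snRNAs, tRNAs and other non-coding RNAs. Many of these annotations overlap: 270 of 925 CUTs and 537 of 847 SUTs share more than 1 nt with another feature outside the genes on their strand, so their values are not independent.

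Densities were set to log2 after adding 0.0120173, the 10th percentile of all values above 0. Features at or above this value in at least 2 libraries were kept, 11485 in all (5725 genes), and 541 were not. Linear models with 1 mean per group were fitted with limma 3.58.1 in R 4.3.3, with a variance trend and two-sided moderated tests. The fit has 6 residual degrees of freedom, and the variance prior adds a median of 3.14. P-values were adjusted by the Benjamini-Hochberg method over all features kept, separately in each comparison, and features under 0.05 are called. The comparisons were FU with wild type and rrp6 with wild type at each time, FU with rrp6 at each time, 100 min with 40 min in each strain or treatment, and the FU by time and rrp6 by time interactions. Tables were handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6. Intervals came from SciPy 1.17.1 and figures from matplotlib 3.10.9.

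Of 37 gene lists fixed for the study, 36 have members in the table. They cover the exosome and its cofactors, histones, G1/S, G2/M and M/G1 genes, pheromone response, a-specific, alpha-specific and haploid-specific genes, and meiosis. They also cover ribosome biogenesis, pseudouridine synthases, RNA polymerases I and III, pyrimidine synthesis and salvage, DNA damage, general stress, heat shock, iron, phosphate, amino acid synthesis, sulfur and methionine. Further lists hold glycolysis, respiration, ergosterol, proteasome, multidrug efflux, cell wall stress and snoRNP genes, mitochondrial genome features, cytosolic ribosomal proteins, snoRNAs and 5 classes of non-coding transcripts. In the lists, 3 gene names had no match. Each list was tested against all other features with limma's camera, with a preset correlation between genes of 0.01 and again with the correlation estimated from the data, and adjusted over the lists. In the 4 comparisons of FU or rrp6 with wild type, only the M/G1 list with FU at 100 min stays called with the estimated correlation. Because camera compares a list with all other features, a list can be called lower while its own median lies above 0.

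The genes named in the text follow a rule. In each comparison of FU or rrp6 with wild type it takes RRP6, then the 5 genes and 3 non-coding features with the largest rise and as many with the largest fall among called features whose libraries all lie on 1 side of both control libraries. From each list that is called or has at least 3 called members it takes the 3 called members with the smallest adjusted p, or the 2 most abundant members where none is called. For time effects and interactions it takes the 5 largest rises and falls. The cyclins CLN1, CLN2, CLN3, CLB1, CLB2, CLB5 and CLB6, and SIC1, are included throughout. The text prints the main ones and summarises the others. The groups, the model, the lists, this rule and most alternatives were chosen before the data were examined.

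The alternatives were a pseudocount 10 times larger and 0.1 times as large, no filter and a stricter one, scaling by the median of ratios over genes or over snoRNAs, quantile normalization, no variance trend, genes only, a minimum log2 change of 1, only the groups compared, the replicate number as a block, and leaving out each library. Chosen after seeing the data were limma-voom on the recovered reads, median of ratios together with the block, leaving out both 40 min libraries with the same replicate number, leaving out single FU or rrp6 libraries for the overlap, and setting the FU effect at 1 time against the rrp6 effect at the other, which share no library. DESeq2 was not run. The deposited values are densities, and the whole-number reads recovered from them were used with limma-voom only. Shares of reads in single libraries carry 95% Wilson intervals, which cover counting error only. The fit was tested on simulated data made by changing 50 features for each fold size: of changes of 2-fold, 4-fold and 8-fold with FU at 40 min, 18%, 58% and 88% were recovered, with 6 false calls among 88. In a separate simulation of 36 lists of features drawn at random, 5 were shifted by 1 on the log2 scale. Camera called 5 of these 5 and 0 unshifted lists with either correlation. Lists drawn at random do not test camera on lists of genes that vary together.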

Results

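Transcription in synchronized yeast was measured in wild-type cells, in wild-type cells with the anti-cancer drug 5-fluorouracil (FU) and in cells that lack RRP6, the gene of a nuclear exosome 3′ exonuclease. The 12 libraries fall into 6 groups of 2 biological replicates: each of the 3 conditions at 40 min and 100 min after synchronization. For replicates 1 and 2, the reads over all features were 23013796 and 21890686 in wild type at 40 min, and 20102931 and 21742500 at 100 min. With FU they were 23924773 and 25873312 at 40 min, and 23591060 and 23108994 at 100 min. In rrp6 they were 26773004 and 27498217 at 40 min, and 26757305 and 27208158 at 100 min. Replicates correlated across genes on the log2 scale with Pearson's r of 0.936 in wild type and 0.951 with FU at 40 min, and at least 0.985 in the other groups; genes are not independent replicates. The snoRNA share of reads separated the 40 min replicates. It was 11.68% (95% Wilson interval 11.67 to 11.69) and 20.24% (20.22 to 20.25) in wild type, and 10.06% (10.05 to 10.08) and 20.86% (20.85 to 20.88) with FU. In the groups at 100 min and in rrp6 it was 14.6% ± 0.571 and 13.6% ± 2.46 (wild type and FU at 100 min), and 10.1% ± 0.191 and 10.2% ± 0.124 (rrp6 at 40 and 100 min; mean ± SD, n = 2).

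Changes are log2 fold changes ± standard error from limma, with 2 libraries per group, and densities are mean ± SD (n = 2) in reads per nucleotide on the deposited scale. This scale gives every library the same total over genes, and the 100 most abundant genes held a smaller share of that total with FU and in rrp6 than in wild type. Their share was 42.3% ± 2.80 and 43.3% ± 0.332 in wild type at 40 and 100 min, 36.2% ± 0.215 and 38.6% ± 0.154 with FU, and 38.2% ± 0.977 and 37.7% ± 0.325 in rrp6. The median gene was higher by 0.37 and 0.30 with FU and by 0.45 and 0.45 in rrp6 at 40 and 100 min, and with median of ratios scaling it lay at 0.016, 0.0019, -0.013 and -0.0062. Medians of gene lists and classes are therefore given relative to the median gene of the comparison. Changes of single genes are on the deposited scale and include the shift. Counts of calls adjusted over the members of a list, not over all features, are given as over the list alone.

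The comparison of wild type with and without FU at 40 min asks which transcripts differ with the drug at the earlier time. Some ribosomal protein genes were lower with FU, and ARO10 and ARO9, 2 genes for the breakdown of aromatic amino acids, were higher. ARO10 (YDR380W, chromosome 4, 1234218 to 1236125), a decarboxylase, rose by 2.39 ± 0.24 (adjusted p = 0.0108), from a density of 0.344 ± 0.0401 to 1.86 ± 0.336. ARO9 (YHR137W, chromosome 8, 375709 to 377250), an aminotransferase, rose by 1.86 ± 0.24 (adjusted p = 0.0226). RPL8A (YHL033C, chromosome 8, 35255 to 36025), a protein of the large ribosomal subunit, fell by 2.03 ± 0.17 (adjusted p = 0.00901), from 19.8 ± 2.89 to 4.85 ± 0.775. Of the cytosolic ribosomal protein genes, 0 of 139 rose and 21 fell (1 and 103 over the list alone). The ribosomal protein median was -1.15 (adjusted p = 4.78e-155, or 0.131 with estimated correlation). Among them RPL28 fell by 1.22 ± 0.23 (adjusted p = 0.0405), RPS8A fell by 0.92 ± 0.17 (adjusted p = 0.0393) and RPL7B, which holds SNR59 on its strand, fell by 1.55 ± 0.25 (adjusted p = 0.0335). The pheromone gene MF(ALPHA)1 (YPL187W, chromosome 16, 193648 to 194145) fell by 1.96 ± 0.28 (adjusted p = 0.0249) and PHM6 (YDR281C, chromosome 4, 1022007 to 1022321), a gene induced by low phosphate, fell by 1.45 ± 0.22 (adjusted p = 0.0266). RRP6 itself was at 0.64 ± 0.21 (adjusted p = 0.106).

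The other lists called with FU at 40 min follow; with estimated correlation their calls end. Of the ribosome biogenesis genes, 4 of 104 rose (22 over the list alone). The ribosome biogenesis median was 0.18 (adjusted p = 4.14e-06, or 0.802 with estimated correlation). Among these were the RNA helicase gene DBP2 at 1.02 ± 0.18, NOC4 at 0.77 ± 0.14 and SDA1 at 0.75 ± 0.15. Of the proteasome genes, 3 of 33 rose (19 over the list alone). The proteasome median was 0.37 (adjusted p = 4.27e-06, or 0.802 with estimated correlation). Among these were RPN12 at 1.12 ± 0.20, PRE9 at 0.85 ± 0.16 and RPT1 at 1.01 ± 0.22. Of the exosome genes, 0 of 21 passed the limma test, with 17 higher and 0 lower at an unadjusted p under 0.05, 0 called by limma-voom, and 16 rose over the list alone. The exosome median was 0.23 (adjusted p = 0.000346, or 0.631 with estimated correlation). Most abundant were the helicase gene MTR4 at 0.46 ± 0.16 and RRP42 at 0.35 ± 0.18. For RNA polymerases I and III, 0 of 27 passed the limma test, with 13 higher and 0 lower at an unadjusted p under 0.05, 0 called by limma-voom, and 8 rose over the list alone. The polymerase median was 0.12 (adjusted p = 0.0321, or 0.802 with estimated correlation). Of the phosphate genes, 1 of 17 fell (1 over the list alone). The phosphate median was -0.44 (adjusted p = 3.01e-09, or 0.253 with estimated correlation). Of the alpha-specific genes, 1 of 4 fell (2 over the list alone). The alpha-specific median was -0.71 (adjusted p = 3.86e-05, or 0.253 with estimated correlation). The sulfur and methionine list was called lower although 2 of 30 rose (3 over the list alone). The sulfur and methionine median was -0.22 (adjusted p = 0.0109, or 0.802 with estimated correlation). The called genes were HOM3 at 0.85 ± 0.16 and SAM1 at 1.00 ± 0.21. Of the glycolysis genes, 0 of 16 passed the limma test, with 0 higher and 1 lower at an unadjusted p under 0.05, 0 called by limma-voom, and 0 rose over the list alone. The glycolysis median was -0.66 (adjusted p = 3.01e-09, or 0.631 with estimated correlation). Of the general stress genes, 0 of 40 passed the limma test, with 0 higher and 0 lower at an unadjusted p under 0.05, 0 called by limma-voom, and 0 rose over the list alone. The general stress median was -0.18 (adjusted p = 1.47e-06, or 0.802 with estimated correlation). On the deposited scale it was 0.20. Of the histone genes, 0 of 10 passed the limma test, with 1 higher and 0 lower at an unadjusted p under 0.05, 0 called by limma-voom, and 0 rose over the list alone. The histone median was -0.42 (but 0.21 with quantile normalization) (adjusted p = 0.00467, or 0.802 with estimated correlation). The cyclins and SIC1 did not pass the test at 40 min. CLN3 was at 0.41 ± 0.52, CLN2 at 0.50 ± 0.39, CLB5 at 0.70 ± 0.27, CLB1 at -0.77 ± 0.38 and SIC1 at 0.51 ± 0.31. Their adjusted p ranged from 0.135 (CLB5) to 0.865 (CLN1).

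Of the 5 non-coding classes tested with FU at 40 min, CUTs rose most often, on the deposited scale. Of the CUTs, 71 of 923 rose and 0 fell (198 and 1 over the list alone). The CUT median was 0.44 (adjusted p = 3.86e-05, or 0.802 with estimated correlation). CUT181 (chromosome 8, 411647 to 412327) rose by 3.22 ± 0.43 (adjusted p = 0.0239), CUT307 (chromosome 13, 652922 to 653050) by 3.16 ± 0.44 (adjusted p = 0.0249) and CUT147 (chromosome 7, 545831 to 546055) by 2.19 ± 0.22 (adjusted p = 0.0108). CUT181 (by CUT180), CUT307 (by CUT306 and CUT308) and CUT147 lie within 1000 nt past SNR71, SNR11 and SNR46. CUTs took 0.167% ± 0.0376 of reads in wild type and 0.293% ± 0.0964 with FU (mean ± SD, n = 2). Of the XUTs, 59 of 1773 rose (108 over the list alone). The XUT median was 0.19 (adjusted p = 0.0650). XUT1049 and SUT465, which overlap, were at 2.64 ± 0.34 and 2.67 ± 0.34. Of the SUTs, 28 of 830 rose (30 over the list alone). The SUT median was 0.19 (adjusted p = 0.0974). Of the MUTs, 14 of 529 rose (14 over the list alone). The MUT median was -0.051 (but 0.16 with median of ratios) (adjusted p = 0.0650). Of the mSUTs, 21 of 625 rose (29 over the list alone). The mSUT median was 0.078 (adjusted p = 0.467). Of the snoRNAs, 1 of 77 fell (0 over the list alone), SNR59. The snoRNA median was -0.26 (but 0.37 with quantile normalization) (adjusted p = 7.32e-08, or 0.802 with estimated correlation).

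In all, 292 features were higher and 27 lower with FU at 40 min. With median of ratios scaling 1 and 4 were called, all of them among the first, and of the 38 named calls 4 stayed: ARO10 (adjusted p = 0.0482), RPL8A (0.0431), MF(ALPHA)1 (0.0482) and PHM6 (0.0431). The CUT median relative to genes was then 0.54 in place of 0.44, and 0 CUTs were called by limma (373 higher at an unadjusted p under 0.05 on the deposited scale, 11 called by limma-voom). Single libraries decided the count, and only ARO10 and RPL8A of the named calls held without any 1 of the 4. Against the mean of the controls, without subtracting the median gene, the CUT median was 0.36 and 1.27 in FU replicates 1 and 2. Replicate 2 had the higher snoRNA share. The tRNAs (few reads, not tested as a list) were at 0.21 and 2.21 in these libraries, and 0.78 relative to genes. CUTs relative to genes were at 0.35 and 0.56 between libraries of the same replicate number, and at -0.52 and 1.44 in the other pairings.

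**Figure D1:**
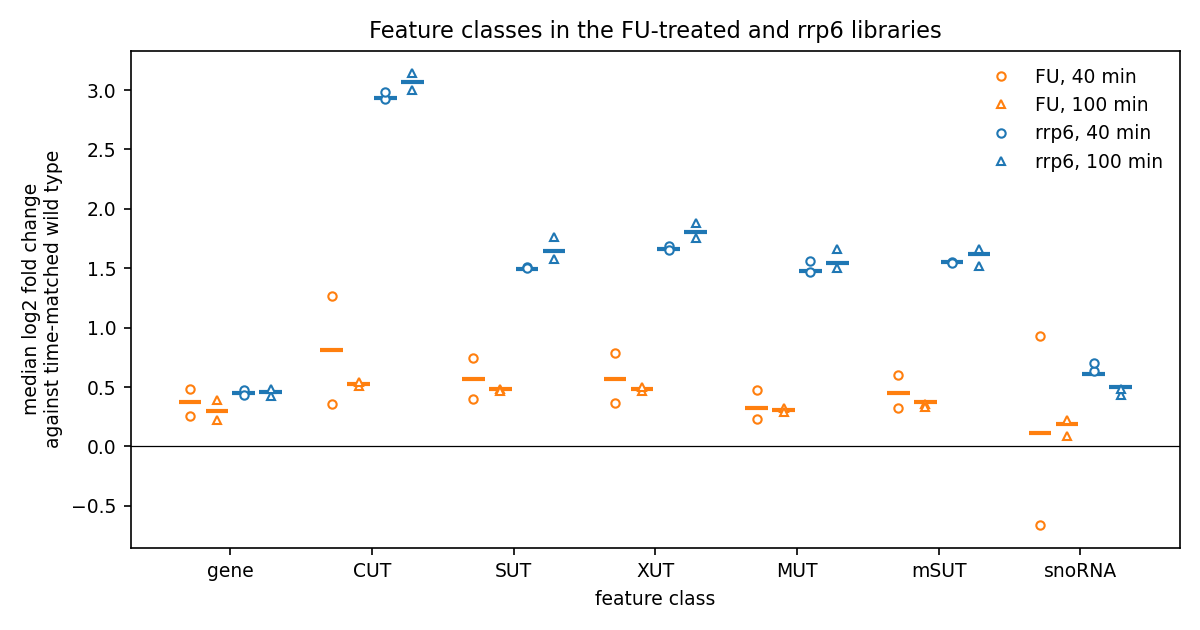
Median log2 fold change (y axis) of protein-coding genes and classes of non-coding transcripts (x axis) with FU (orange) and in rrp6 (blue) against wild type at the same time, at 40 min (circles) and 100 min (triangles). Bars are medians over all features of a class and open points the medians of single treated libraries against the mean of the 2 controls. CUTs reach 2.93 and 3.07 in rrp6 and 0.81 and 0.52 with FU, where the libraries at 40 min lie at 0.36 and 1.27.

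The comparison with FU at 100 min asks how the drug's effect stands at the later time. Some genes of the DNA damage response were higher. HUG1 (YML058W-A, chromosome 13, 158760 to 158966), an inhibitor of ribonucleotide reductase that is induced by damaged DNA, rose by 4.29 ± 0.28 (adjusted p = 0.000798), from 0.128 ± 0.0183 to 2.73 ± 0.354. Subunits of ribonucleotide reductase rose with it: RNR2 (YJL026W, chromosome 10, 392404 to 393603) by 3.04 ± 0.27 (adjusted p = 0.00169), RNR3 (YIL066C, chromosome 9, 238099 to 240708) by 3.09 ± 0.30 (adjusted p = 0.00226) and RNR4 (YGR180C, chromosome 7, 855264 to 856301) by 3.25 ± 0.40 (adjusted p = 0.00615). PLM2 (YDR501W, chromosome 4, 1451353 to 1452918), a gene of the damage response, rose by 3.33 ± 0.41 (adjusted p = 0.00615). The density of RNR2 went from 4.12 ± 0.475 to 34.3 ± 7.36. Of the DNA damage genes, 9 of 26 rose (13 over the list alone). The DNA damage median was 0.60 (adjusted p = 4.93e-08, or 0.350 with estimated correlation). In the G1/S list 5 of 41 rose (12 over the list alone). The G1/S median was 0.22 (adjusted p = 0.0446, or 0.875 with estimated correlation). The called genes include NRM1, a repressor of G1/S transcription, at 2.34 ± 0.21, and RFA3, a subunit of replication protein A, at 1.32 ± 0.21 (adjusted p = 0.0166, and 0.0525 with median of ratios).

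**Figure D2:**
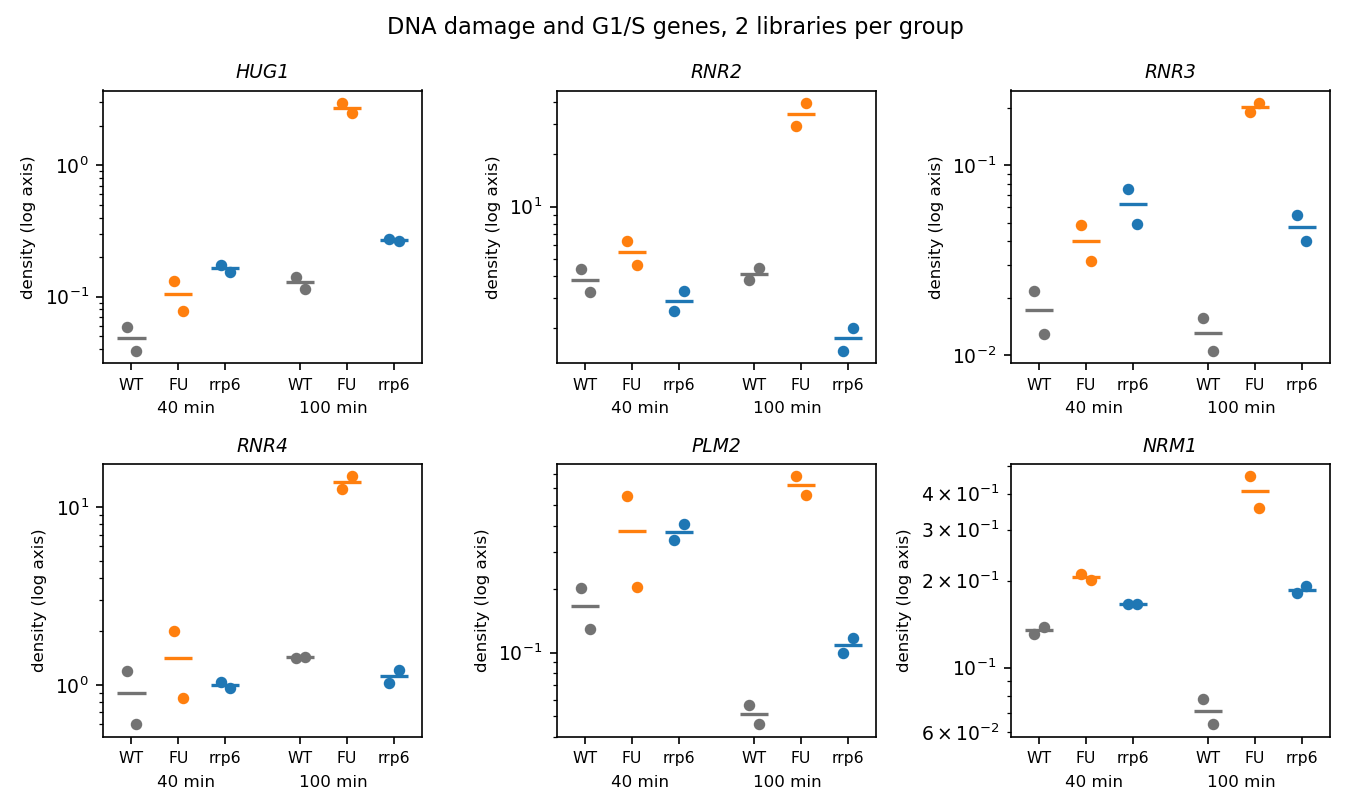
Density (reads per nucleotide on the deposited scale, log axis) of HUG1, RNR2, RNR3, RNR4, PLM2 and NRM1 in the 6 groups; points are libraries and bars are means of 2. HUG1 is at 2.73 ± 0.354 with FU at 100 min (mean ± SD) and at 0.128 ± 0.0183 in wild type.

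Genes that act at the end of mitosis were lower with FU at 100 min. EGT2 (YNL327W, chromosome 14, 24048 to 27173), a cell wall protein of mother and daughter separation, fell by 5.76 ± 0.45 (adjusted p = 0.00117), from 3.40 ± 0.222 to 0.0510 ± 0.00221. DSE4 (YNR067C, chromosome 14, 755746 to 759099), a glucanase of daughter cells, fell by 5.04 ± 0.49 (adjusted p = 0.00226), and SCW11 (YGL028C, chromosome 7, 441281 to 442909), another glucanase, fell by 3.96 ± 0.51 (adjusted p = 0.00716). PCL9 (YDL179W, chromosome 4, 138291 to 139205), a cyclin of the kinase Pho85, fell by 3.77 ± 0.34 (adjusted p = 0.00169). DSE3 (YOR264W, chromosome 15, 818866 to 820158) fell by 3.74 ± 0.33 (adjusted p = 0.00169). AMN1 (YBR158W, chromosome 2, 556549 to 558198), an antagonist of mitotic exit, fell by 3.42 ± 0.25 (adjusted p = 0.000798). SIC1 (YLR079W, chromosome 12, 286820 to 287674), an inhibitor of mitotic cyclin-kinase complexes, fell by 1.66 ± 0.31 (adjusted p = 0.0299). Of the M/G1 genes, 13 of 30 fell (18 over the list alone). The M/G1 median was -1.63 (adjusted p = 3.37e-46, or 0.0433 with estimated correlation). Of the G2/M genes, 2 of 24 fell (3 over the list alone). The G2/M median was -0.63 (adjusted p = 4.61e-09, or 0.201 with estimated correlation). Among these were the kinase gene KIN3 at -2.27 ± 0.33 and HOF1, a protein of cytokinesis, at -2.37 ± 0.39. The cyclins did not pass the test; CLN2 was at -1.04 ± 0.39, CLB1 at 0.71 ± 0.38, CLB2 at 0.16 ± 0.27 and CLN1 at 0.57 ± 0.39, with adjusted p from 0.174 (CLN2) to 0.747 (CLB2).

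**Figure D3:**
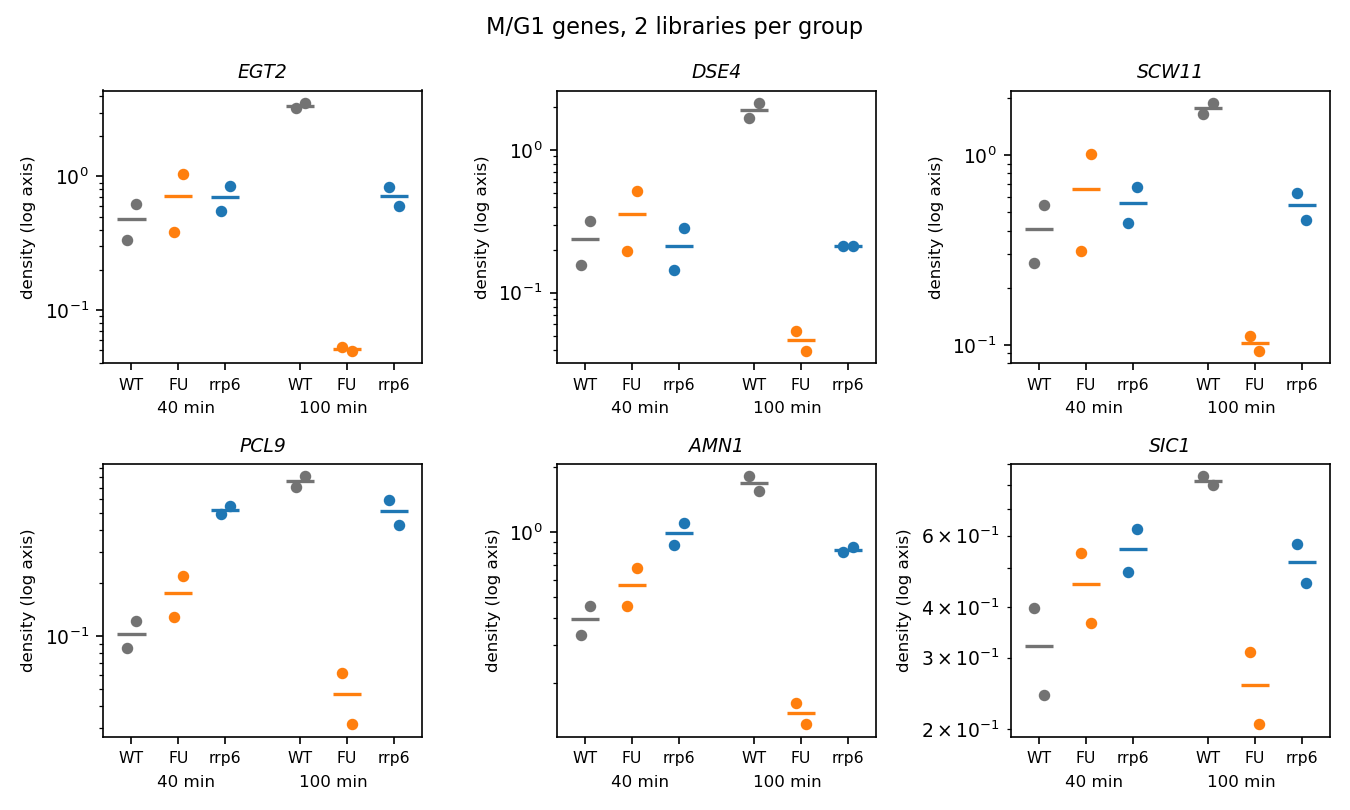
Density (reads per nucleotide on the deposited scale, log axis) of EGT2, DSE4, SCW11, PCL9, AMN1 and SIC1 in the 6 groups; points are libraries and bars are means of 2. EGT2 is at 3.40 ± 0.222 in wild type at 100 min (mean ± SD) and at 0.0510 ± 0.00221 with FU.

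Metabolic lists with FU at 100 min follow, of which none is called with estimated correlation. Of the sulfur and methionine genes, 0 of 30 rose and 7 fell (1 and 11 over the list alone). The sulfur and methionine median was -0.67 (adjusted p = 8.10e-19, or 0.129 with estimated correlation). MET17 (YLR303W, chromosome 12, 732542 to 733876), which makes homocysteine, fell by 2.17 ± 0.24 (adjusted p = 0.00399), SAM1, which makes S-adenosylmethionine, was at -1.49 ± 0.21 and the methionine permease MUP1 at -1.32 ± 0.19. Of the phosphate genes, 0 of 17 rose and 3 fell (1 and 7 over the list alone). The phosphate median was -0.71 (adjusted p = 1.70e-15, or 0.108 with estimated correlation). Among these were the acid phosphatases PHO12 (YHR215W, chromosome 8, 552099 to 553502) at -2.80 ± 0.30 and PHO5 at -2.16 ± 0.30, and PHM6 at -2.38 ± 0.22. In the amino acid list 5 of 39 rose (14 over the list alone). The amino acid median was 0.58 (adjusted p = 0.000110, or 0.569 with estimated correlation). Among these were the arginine genes ARG3 (YJL088W, chromosome 10, 268799 to 269815) at 3.07 ± 0.35 and ARG1 at 2.68 ± 0.37, and SER3, which overlaps SRG1, at 1.20 ± 0.18. Of the proteasome genes, 3 of 33 rose (17 over the list alone). The proteasome median was 0.37 (adjusted p = 3.14e-07, or 0.586 with estimated correlation). Among these were PUP2 at 0.84 ± 0.15, RPT1 at 1.19 ± 0.22 and RPN11 at 0.87 ± 0.17. In the pyrimidine list 1 of 27 fell (1 over the list alone), IMD2, an IMP dehydrogenase of GTP synthesis, at -1.80 ± 0.29. The pyrimidine median was -0.48 (adjusted p = 2.43e-08, or 0.108 with estimated correlation). In the iron list 1 of 31 rose and 1 fell (1 and 1 over the list alone), the heme oxygenase HMX1 at 2.30 ± 0.45 and the siderophore transporter ARN2 at -1.15 ± 0.21. The iron median was -0.14 (adjusted p = 0.0355, or 0.645 with estimated correlation). Of the glycolysis genes, 0 of 16 passed the limma test, with 0 higher and 8 lower at an unadjusted p under 0.05, 0 called by limma-voom, and 5 fell over the list alone. The glycolysis median was -1.03 (adjusted p = 8.10e-19, or 0.141 with estimated correlation). Of the heat shock genes, 0 of 22 passed the limma test, with 0 higher and 1 lower at an unadjusted p under 0.05, 0 called by limma-voom, and 0 rose over the list alone. The heat shock median was -0.39 (adjusted p = 0.00101, or 0.855 with estimated correlation). On the deposited scale the heat shock median was -0.09 and the mean 0.055. The respiration list was not called (adjusted p = 0.542), though 3 of 47 rose (6 over the list alone): COX7, COX12 and ATP14 at 1.04, 0.95 and 0.94. In the ergosterol list 1 of 24 rose (5 over the list alone), ERG7 at 0.73 ± 0.14. The ergosterol median was 0.067 (adjusted p = 0.0319, or 0.510 with estimated correlation). In the multidrug efflux list 1 of 15 rose (1 over the list alone), SNQ2 at 0.99 ± 0.17. The multidrug efflux median was -0.47 (adjusted p = 0.0291, or 0.569 with estimated correlation). On that scale the efflux median was -0.17 and the mean 0.014. Of the ribosomal protein genes, 1 of 139 fell (1 over the list alone), RPL8A at -1.69 ± 0.17. The ribosomal protein median was -0.41 (adjusted p = 7.65e-19, or 0.550 with estimated correlation). MF(ALPHA)1 was at -3.17 ± 0.28, and of the alpha-specific genes 0 of 4 rose and 1 fell (1 and 2 over the list alone). The alpha-specific median was -1.03 (adjusted p = 5.55e-05, or 0.141 with estimated correlation). In the haploid-specific list 1 of 11 fell (1 over the list alone), AMN1. The haploid-specific median was -0.24 (adjusted p = 0.00126, or 0.374 with estimated correlation).

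On the deposited scale fewer features of each of the 5 non-coding classes rose with FU at 100 min than at 40 min. This did not hold with median of ratios, nor, except for CUTs, with limma-voom. With median of ratios 6 CUTs, 8 XUTs, 5 SUTs, 5 MUTs and 1 mSUT were called higher, while all 5 calls at 40 min were genes, and limma-voom called 11 and 8 CUTs, 13 and 25 XUTs, 9 and 11 SUTs, 1 and 7 MUTs, and 5 and 5 mSUTs higher at 40 and 100 min. CUT526 (chromosome 4, 1233561 to 1233681) rose by 2.96 ± 0.33 (adjusted p = 0.00399) and CUT147 by 2.01 ± 0.22 (adjusted p = 0.00380). SUT328 (chromosome 14, 335305 to 336497) fell by 2.14 ± 0.25 (adjusted p = 0.00448) and SUT1290 fell by 2.11 ± 0.28 (adjusted p = 0.00735). MUT729 had 0 reads in both wild-type libraries at 100 min, and its density with FU was 0.172 ± 0.0109 (adjusted p = 0.000798). Of the CUTs, 16 of 923 rose (14 over the list alone). The CUT median was 0.23 (adjusted p = 0.186). Of the XUTs, 36 of 1773 rose and 1 fell (40 and 1 over the list alone). The XUT median was 0.18 (adjusted p = 0.0339, or 0.875 with estimated correlation). Among these were XUT0648, which covers SUT264, at 2.04 ± 0.22 and XUT0862 at 2.49 ± 0.28. Of the SUTs, 13 of 830 rose and 1 fell (22 and 1 over the list alone). The SUT median was 0.18 (adjusted p = 0.0675). Of the MUTs, 8 of 529 rose (8 over the list alone). The MUT median was 0.01 (but -0.018 with quantile normalization) (adjusted p = 0.623). Of the mSUTs, 9 of 625 rose and 1 fell (2 and 1 over the list alone). The mSUT median was 0.073 (but -0.0027 with quantile normalization) (adjusted p = 0.623). Of the snoRNAs, 0 of 77 passed the limma test, with 4 higher and 1 lower at an unadjusted p under 0.05, 0 called by limma-voom, and 0 rose over the list alone. The snoRNA median was -0.11 (but 0.20 with quantile normalization) (adjusted p = 2.35e-05, or 0.875 with estimated correlation). In all, 200 features were higher and 47 lower with FU at 100 min, and with median of ratios 56 and 63, of which 56 and 46 are the same; 11 of 55 named calls ended, among them COX7, ATP14, COX12, ERG7, PUP2, RPT1, RPN11 and SNQ2. The count was 34 without either wild-type library, 45 without FU replicate 1 and 41 without FU replicate 2. Calls of 18 of the 55 held without any 1 library, including HUG1, RNR2, RNR3, NRM1, EGT2, DSE3, DSE4, PCL9, AMN1, PHM6 and RPL8A. Calls of 24 ended without each of the 4, including RNR4 (highest adjusted p = 0.0682), PLM2 (0.0696), SCW11 (0.0779), SIC1 (0.185), SAM1, HMX1, ARN2, IMD2, ARG1, MUP1 and SER3.

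The comparison of rrp6 with wild type shows which transcripts differ when the nuclear exosome lacks this exonuclease. RRP6 itself fell by 3.81 ± 0.21 (adjusted p = 9.10e-06) at 40 min and fell by 3.69 ± 0.21 (adjusted p = 9.01e-06) at 100 min, with densities of 0.0728 ± 0.00753 and 0.0602 ± 0.0133 left in the mutant. Nearly all CUTs, which the exosome degrades, were higher. Of the CUTs, 889 of 923 rose and 1 fell (900 and 2 over the list alone) at 40 min and 883 of 923 rose and 3 fell (893 and 3 over the list alone) at 100 min. The CUT median was 2.48 and 2.62 (adjusted p = 9.41e-25 and 4.64e-23, or 0.425 and 0.301 with estimated correlation). CUTs took 1.82% ± 0.168 and 1.52% ± 0.185 of reads in rrp6, and 0.167% ± 0.0376 and 0.140% ± 0.0130 in wild type (mean ± SD, n = 2). CUT222 (chromosome 10, 664462 to 664710), past SNR3, by CUT221 and CUT223, rose by 9.08 ± 0.57 (adjusted p = 1.51e-05) and 8.45 ± 0.57 (adjusted p = 1.53e-05). Its density at 40 min went from 0.0620 ± 0.0600 to 33.4 ± 9.24. CUT147 rose by 5.50 ± 0.22 (adjusted p = 5.99e-06) and 5.89 ± 0.22 (adjusted p = 4.21e-06).

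The other classes were also higher in rrp6. Of the XUTs, 1438 of 1773 rose and 3 fell (1479 and 4 over the list alone) at 40 min and 1493 of 1773 rose and 7 fell (1529 and 7 over the list alone) at 100 min. The XUT median was 1.21 and 1.35 (adjusted p = 1.15e-09 and 4.07e-11, or 0.497 and 0.301 with estimated correlation). Of the SUTs, 636 of 830 rose and 4 fell (665 and 4 over the list alone) at 40 min and 704 of 830 rose and 3 fell (715 and 3 over the list alone) at 100 min. The SUT median was 1.04 and 1.19 (adjusted p = 6.32e-06 and 8.75e-08, or 0.571 and 0.338 with estimated correlation). Of the MUTs, 429 of 529 rose and 1 fell (441 and 1 over the list alone) at 40 min and 443 of 529 rose and 1 fell (452 and 1 over the list alone) at 100 min. The MUT median was 1.02 and 1.09 (adjusted p = 1.22e-06 and 1.69e-06, or 0.425 and 0.301 with estimated correlation). Of the mSUTs, 466 of 625 rose and 3 fell (479 and 3 over the list alone) at 40 min and 478 of 625 rose and 3 fell (488 and 5 over the list alone) at 100 min. The mSUT median was 1.10 and 1.17 (adjusted p = 0.000130 and 0.000486, or 0.425 and 0.301 with estimated correlation). With quantile normalization the XUT and SUT medians were 0.11 and -0.0045 at 40 min, without subtracting the median gene, which lay at -0.44. Of the snoRNAs, 23 of 77 rose and 6 fell (23 and 5 over the list alone) at 40 min and 26 of 77 rose and 5 fell (24 and 4 over the list alone) at 100 min. The snoRNA median was 0.16 and 0.047 (adjusted p = 0.000109 and 3.21e-05, or 0.802 and 0.731 with estimated correlation). This list was called lower against all other features. SNR62 (chromosome 15, 409765 to 409864) rose by 4.69 ± 0.41 (adjusted p = 4.25e-05) and 4.57 ± 0.41 (adjusted p = 4.04e-05), and SNR61 by 3.87 ± 0.38 (adjusted p = 6.80e-05) and 3.43 ± 0.38 (adjusted p = 0.000100). SNR24, inside ASC1, fell by 2.07 ± 0.36 (adjusted p = 0.00109) at 40 min, and SNR86 fell by 2.38 ± 0.34 (adjusted p = 0.000379) at 100 min.

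Among genes, the largest rises in rrp6 were in genes with little RNA in wild type. REC104 (YHR157W, chromosome 8, 412907 to 413455), a protein of meiotic recombination, rose by 5.27 ± 0.66 (adjusted p = 0.000197) and 4.49 ± 0.66 (adjusted p = 0.000409). YDR042C (chromosome 4, 540601 to 541203), past SNR47, rose by 4.70 ± 0.35 (adjusted p = 2.68e-05) and 5.13 ± 0.35 (adjusted p = 1.62e-05). FLX1 (YIL134W, chromosome 9, 97395 to 98330), past SNR68, rose by 4.57 ± 0.17 (adjusted p = 4.96e-06) at 40 min, and USE1 (YGL098W, chromosome 7, 317342 to 318079), past SNR82, by 4.45 ± 0.26 (adjusted p = 9.01e-06) at 100 min. Against its snoRNA only USE1 was called. NRD1 (YNL251C, chromosome 14, 172588 to 174315), which ends transcription of many non-coding RNAs, rose by 2.94 ± 0.24 (adjusted p = 3.31e-05) and 3.0 ± 0.24 (adjusted p = 2.50e-05), and its helicase partner SEN1 rose by 1.42 ± 0.20 (adjusted p = 0.000381) and 1.39 ± 0.20 (adjusted p = 0.000388). Of the exosome genes, 16 of 21 rose and 1 fell (17 and 1 over the list alone) at 40 min and 12 of 21 rose and 1 fell (13 and 1 over the list alone) at 100 min, and the list was not called (adjusted p = 0.421 and 0.971). SER3 (YER081W, chromosome 5, 322686 to 324095), of serine synthesis, rose by 2.96 ± 0.18 (adjusted p = 9.24e-06) at 100 min. CLB2 (YPR119W, chromosome 16, 771653 to 773128), a mitotic cyclin, rose by 1.62 ± 0.27 (adjusted p = 0.000969) and 0.93 ± 0.27 (adjusted p = 0.0156); with median of ratios the adjusted p was 0.0120 and 0.237.

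Some abundant metabolic genes were lower in rrp6. ENO2 (YHR174W, chromosome 8, 451327 to 452640), an enolase, fell by 3.71 ± 0.30 (adjusted p = 3.41e-05) and fell by 4.52 ± 0.30 (adjusted p = 1.53e-05). TDH3 (YGR192C, chromosome 7, 882812 to 883810), a glyceraldehyde-3-phosphate dehydrogenase, fell by 3.25 ± 0.27 (adjusted p = 3.69e-05) and fell by 4.28 ± 0.27 (adjusted p = 1.30e-05). The density of TDH3 at 100 min went from 129.8 ± 8.90 to 6.77 ± 1.62. PGK1 (YCR012W, chromosome 3, 137746 to 138996), the phosphoglycerate kinase, fell by 5.24 ± 0.41 (adjusted p = 2.47e-05) at 100 min. Of the glycolysis genes, 11 of 16 fell (11 over the list alone) at 40 min and 15 of 16 fell (15 over the list alone) at 100 min. The glycolysis median was -2.23 and -3.13 (adjusted p = 1.21e-23 and 5.00e-32, or 0.10 and 0.0722 with estimated correlation). PHM6 fell by 3.16 ± 0.22 (adjusted p = 2.01e-05) and fell by 3.91 ± 0.22 (adjusted p = 9.01e-06). Of the phosphate genes, 8 of 17 fell (6 over the list alone) at 40 min and 1 of 17 rose and 10 fell (1 and 10 over the list alone) at 100 min. The phosphate median was -0.98 and -1.47 (adjusted p = 4.65e-13 and 2.23e-16, or 0.10 and 0.0722 with estimated correlation). FET3 (YMR058W, chromosome 13, 388822 to 390732), an oxidase of iron uptake, fell by 3.41 ± 0.31 (adjusted p = 4.85e-05) at 40 min. Of the iron genes, 7 of 31 rose and 8 fell (7 and 8 over the list alone) at 40 min and 6 of 31 rose and 13 fell (6 and 13 over the list alone) at 100 min. The iron median was -0.68 and -0.79 (adjusted p = 1.76e-10 and 3.11e-14, or 0.10 and 0.0722 with estimated correlation). SAM2 (YDR502C, chromosome 4, 1453310 to 1454464), which makes S-adenosylmethionine, fell by 4.65 ± 0.54 (adjusted p = 0.000127), SAM1 fell by 3.55 ± 0.21 (adjusted p = 9.14e-06) and MET17 fell by 3.48 ± 0.24 (adjusted p = 1.76e-05) at 100 min. Of the sulfur and methionine genes, 8 of 30 rose and 1 fell (5 and 1 over the list alone) at 40 min and 6 of 30 rose and 13 fell (7 and 13 over the list alone) at 100 min. The sulfur and methionine median was -0.0076 (but 0.032 with median of ratios) and -0.90 (adjusted p = 0.0142 and 2.23e-16, or 0.658 and 0.108 with estimated correlation). Of the ribosomal protein genes, 3 of 139 rose and 114 fell (4 and 118 over the list alone) at 40 min and 5 of 139 rose and 14 fell (4 and 6 over the list alone) at 100 min. The ribosomal protein median was -1.47 and -0.64 (but 0.24 with quantile normalization) (adjusted p = 1.62e-90 and 2.82e-28, or 0.10 and 0.301 with estimated correlation). RPL2A was at -1.46 ± 0.21 and RPS9A at 1.93 ± 0.28 at 40 min.

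**Figure D4:**
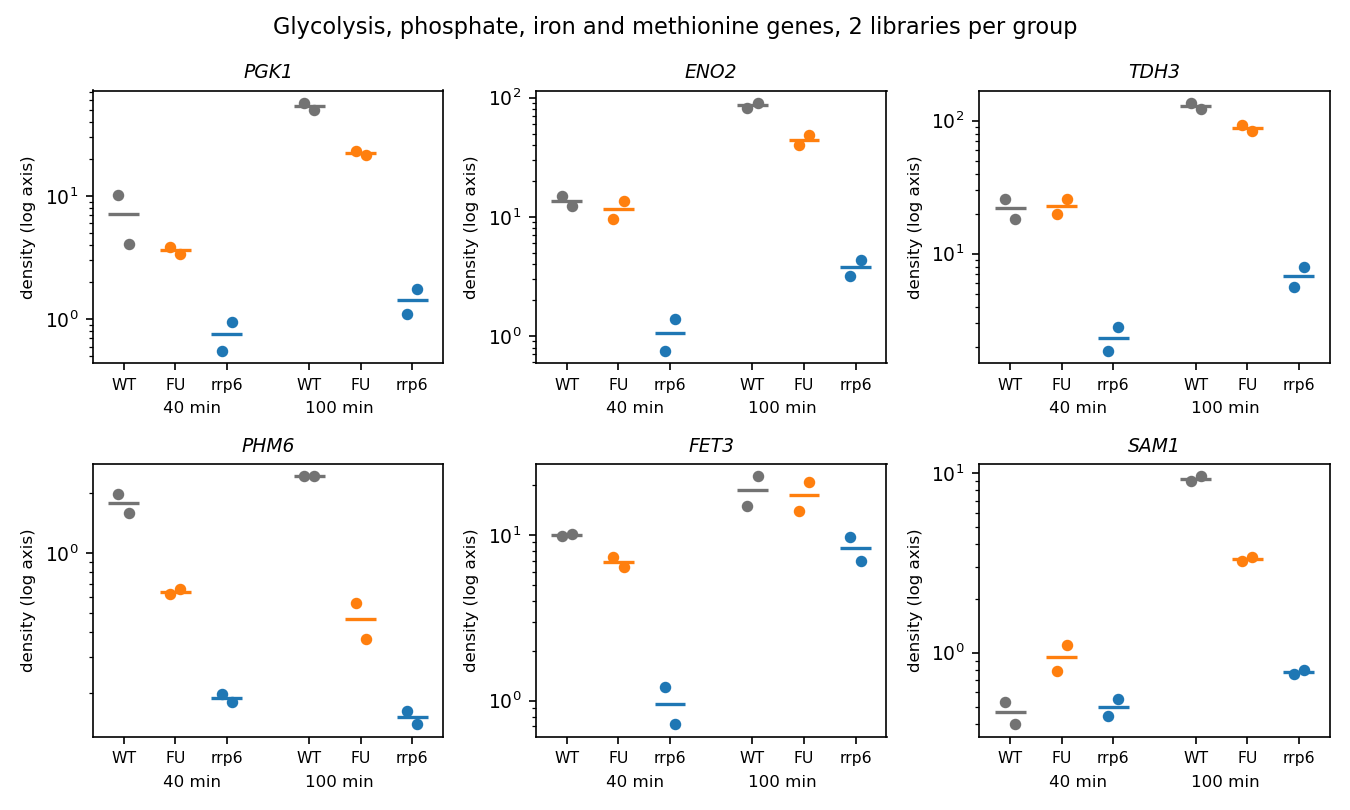
Density (reads per nucleotide on the deposited scale, log axis) of PGK1, ENO2, TDH3, PHM6, FET3 and SAM1 in the 6 groups; points are libraries and bars are means of 2. PGK1 is at 53.5 ± 4.85 in wild type at 100 min (mean ± SD) and at 1.44 ± 0.465 in rrp6.

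Cell cycle genes in rrp6 are given for both times. Of the M/G1 genes, 15 of 30 rose (13 over the list alone) at 40 min and 2 of 30 rose and 7 fell (1 and 6 over the list alone) at 100 min. The M/G1 median was 0.31 and -0.95 (adjusted p = 0.711 and 2.22e-14, or 0.952 and 0.108 with estimated correlation). At 100 min DSE4 was at -3.09 ± 0.49 and EGT2 at -2.24 ± 0.45. Of the G1/S genes, 11 of 41 rose (4 over the list alone) at 40 min and 6 of 41 rose and 3 fell (5 and 2 over the list alone) at 100 min. The G1/S median was 0.10 and -0.54 (adjusted p = 0.266 and 5.72e-09, or 0.802 and 0.301 with estimated correlation). HCM1, a forkhead factor of S phase, was at 1.41 ± 0.19 at 100 min. Of the G2/M genes, 15 of 24 rose (15 over the list alone) at 40 min and 14 of 24 rose (14 over the list alone) at 100 min. The G2/M median was 0.67 and 0.61 (adjusted p = 0.421 and 0.704). CDC20, an activator of the anaphase-promoting complex, was at 1.82 ± 0.24 and IQG1, a protein of cytokinesis, at 1.91 ± 0.22 at 40 min. Of the histone genes, 1 of 10 rose (0 over the list alone) at 40 min and 3 of 10 rose (2 over the list alone) at 100 min. The histone median was -0.38 (but 0.68 with quantile normalization) and 0.31 (adjusted p = 0.0150 and 0.572, or 0.658 and 0.888 with estimated correlation). HTB2 was at 0.86 ± 0.25 and 1.55 ± 0.25. Of the DNA damage genes, 12 of 26 rose (11 over the list alone) at 40 min and 10 of 26 rose and 1 fell (10 and 1 over the list alone) at 100 min. The DNA damage median was 0.29 (but -0.015 with quantile normalization) and 0.26 (but -0.34 with quantile normalization) (adjusted p = 0.991 and 0.341). DIN7 was at 2.47 ± 0.27 at 100 min. SIC1 was at 0.81 ± 0.31 and -0.66 ± 0.31 (adjusted p = 0.0482 and 0.0888, and 0.305 and 0.00448 with median of ratios). CLB1 was at 0.70 ± 0.38 and 1.15 ± 0.38 (adjusted p = 0.146 and 0.0272, and 0.104 at 100 min with median of ratios). CLN1, CLN2, CLN3, CLB5 and CLB6 did not pass the test at either time.

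The remaining lists in rrp6 cover other metabolism and stress. For ribosome biogenesis, 60 of 104 rose and 1 fell (60 and 1 over the list alone) at 40 min and 38 of 104 rose and 1 fell (28 and 0 over the list alone) at 100 min. The ribosome biogenesis median was 0.23 and 0.037 (adjusted p = 0.565 and 0.238). For RNA polymerases I and III, 16 of 27 rose (16 over the list alone) at 40 min and 10 of 27 rose (8 over the list alone) at 100 min. The polymerase median was 0.21 and 0.13 (adjusted p = 0.565 and 0.287). For pseudouridine synthases, 9 of 13 rose (9 over the list alone) at 40 min and 5 of 13 rose (4 over the list alone) at 100 min. The pseudouridine synthase median was 0.17 and -0.09 (but 0.32 with quantile normalization) (adjusted p = 0.999 and 0.287). For cell wall stress, 6 of 16 rose (6 over the list alone) at 40 min and 9 of 16 rose and 1 fell (9 and 1 over the list alone) at 100 min. The cell wall median was 0.22 and 0.50 (adjusted p = 0.312 and 0.238). The kinase gene SLT2 of that list was at 1.29 ± 0.24 and 1.59 ± 0.24. For snoRNP genes, 4 of 13 rose (3 over the list alone) at 40 min and 2 of 13 rose (2 over the list alone) at 100 min. The snoRNP median was -0.23 (but 0.53 with quantile normalization) and -0.19 (but 0.38 with quantile normalization) (adjusted p = 0.255 and 0.0449, or 0.802 and 0.692 with estimated correlation). For pyrimidine synthesis, 9 of 27 rose (8 over the list alone) at 40 min and 4 of 27 rose and 3 fell (3 and 1 over the list alone) at 100 min. The pyrimidine median was -0.21 (but 0.33 with quantile normalization) and -0.62 (adjusted p = 0.0764 and 6.55e-09, or 0.620 and 0.0722 with estimated correlation). For ergosterol, 4 of 24 rose and 4 fell (4 and 4 over the list alone) at 40 min and 5 of 24 rose and 4 fell (3 and 4 over the list alone) at 100 min. The ergosterol median was -0.53 and -0.49 (but 0.064 with quantile normalization) (adjusted p = 9.01e-07 and 5.36e-07, or 0.10 and 0.0816 with estimated correlation). ERG11 was at -0.78 ± 0.14 and -0.66 ± 0.14. For multidrug efflux, 4 of 15 rose (1 over the list alone) at 40 min and 2 of 15 rose and 1 fell (1 and 0 over the list alone) at 100 min. The multidrug efflux median was -0.081 (but 0.031 with quantile normalization) and -0.52 (adjusted p = 0.0814 and 0.000238, or 0.658 and 0.301 with estimated correlation). For amino acid synthesis, 7 of 39 rose and 4 fell (6 and 4 over the list alone) at 40 min and 21 of 39 rose and 3 fell (23 and 3 over the list alone) at 100 min. The amino acid median was -0.28 (but 0.15 with quantile normalization) and 0.32 (adjusted p = 7.24e-06 and 0.589, or 0.502 and 0.893 with estimated correlation). For general stress, 6 of 40 rose and 1 fell (3 and 0 over the list alone) at 40 min and 9 of 40 rose (6 over the list alone) at 100 min. The general stress median was -0.027 (but 0.01 with median of ratios) and 0.65 (adjusted p = 0.000105 and 0.0376, or 0.658 and 0.756 with estimated correlation), both called lower. For heat shock, 3 of 22 rose (3 over the list alone) at 40 min and 2 of 22 rose (1 over the list alone) at 100 min. The heat shock median was 0.024 (but -0.01 with quantile normalization) and -0.32 (adjusted p = 0.0102 and 8.69e-05, or 0.802 and 0.637 with estimated correlation), again called lower. For respiration, 2 of 47 rose and 3 fell (0 and 0 over the list alone) at 40 min and 16 of 47 rose and 1 fell (12 and 1 over the list alone) at 100 min. The respiration median was -0.46 and -0.16 (but 0.34 with quantile normalization) (adjusted p = 4.11e-10 and 0.000196, or 0.516 and 0.692 with estimated correlation). For proteasome genes, 2 of 33 rose (0 over the list alone) at 40 min and 4 of 33 rose (0 over the list alone) at 100 min. The proteasome median was -0.22 (but 0.066 with quantile normalization) and -0.24 (but 0.28 with quantile normalization) (adjusted p = 0.000416 and 0.000889, or 0.658 and 0.692 with estimated correlation). For alpha-specific genes, 1 of 4 rose and 2 fell (2 and 2 over the list alone) at 40 min and 2 of 4 rose and 2 fell (2 and 2 over the list alone) at 100 min. The alpha-specific median was -0.73 and -0.46 (adjusted p = 0.00552 and 0.00518, or 0.425 and 0.301 with estimated correlation). MF(ALPHA)1 was at -1.65 ± 0.28 and -3.16 ± 0.28.

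In all, 6223 features were higher and 327 lower in rrp6 at 40 min, and 6553 and 322 at 100 min. With median of ratios 4162 and 817 were called at 40 min and 4743 and 953 at 100 min. Genes alone numbered 1848 higher and 301 lower at 40 min on the deposited scale, and 703 and 760 with median of ratios; at 100 min they numbered 1975 and 295, and 924 and 893. That scaling ended 19 of 111 named calls at 40 min, among them SIC1 and HTB2, and 15 of 116 at 100 min, among them CLB1 and CLB2. Without any 1 of the 4 libraries 95 of the 111 and 103 of the 116 named calls held, and CLB1 and SUT1068 were among 4 that ended without each at 100 min.

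The direct comparison of FU-treated wild type with rrp6 uses no shared control. CUTs were lower with FU than in rrp6 at both times. Of the 923, 806 were lower and 1 higher at 40 min, with a median of -2.08, and 853 and 1 at 100 min, with a median of -2.40. The CUT list had adjusted p = 5.90e-31, or 0.378 with estimated correlation at 40 min, and adjusted p = 8.76e-30, or 0.314 with estimated correlation at 100 min. CUT147 differed by -3.31 ± 0.22 (adjusted p = 0.000102) and -3.87 ± 0.22 (adjusted p = 4.41e-05). Of the XUTs 984 and 1220 and of the SUTs 406 and 545 were lower with FU. Of the glycolysis genes, 9 of 16 were higher (9 over the list alone) at 40 min and 12 of 16 were higher (12 over the list alone) at 100 min. The glycolysis median was 1.34 and 2.26 (adjusted p = 3.23e-14 and 1.01e-18, or 0.261 and 0.247 with estimated correlation). ENO2 was at 3.47 ± 0.30 and 3.56 ± 0.30. Of the proteasome genes, 7 of 33 were higher (6 over the list alone) at 40 min and 8 of 33 were higher (7 over the list alone) at 100 min. The proteasome median was 0.62 and 0.60 (adjusted p = 2.47e-15 and 3.46e-15, or 0.378 and 0.314 with estimated correlation). At 100 min HUG1 was at 3.28 ± 0.28 and RNR4 at 3.61 ± 0.40, and of the DNA damage genes 8 of 26 were higher and 4 were lower (8 and 4 over the list alone). The DNA damage list had adjusted p = 7.90e-07, or 0.314 with estimated correlation. In all, 293 features were higher and 3750 lower with FU than in rrp6 at 40 min (381 and 2926 with median of ratios), and 384 and 4738 at 100 min (590 and 3856). The count at 40 min was 2496 without rrp6 replicate 1 and 2240 without rrp6 replicate 2, and that at 100 min was 3205 without rrp6 replicate 2.

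The overlap of the drug and mutant effects asks whether FU and the loss of Rrp6 move the same features. At 40 min, 281 features were higher and 24 lower in both, where 158 and 0.769 would follow from the counts alone, and 0 were called in opposite directions by limma. At 100 min 180 were higher and 27 lower in both, against 114 and 1.32, and 4 went in opposite directions. Genes in both include PHM6, MF(ALPHA)1 and DBP2 at 40 min, and PHO12, MET17, SAM1 and ARG3 at 100 min. Both effects are taken against the same wild-type libraries. Part of the excess may come from them. In 100 simulations without any effect calls were bunched in few runs (at most 1002 and 2114 higher with FU), which gives no overlap to compare. With the simulated range in brackets, the covariance of the effects over all features was 0.383 (-0.111 to 0.362) at 40 min and 0.321 (-0.223 to 0.786) at 100 min, and over genes 0.168 (-0.104 to 0.288) and 0.223 (-0.142 to 0.646). The correlation over all features was 0.636 (-0.865 to 0.976) and 0.479 (-0.758 to 0.985), so all of these lay within the range but the covariance over all features at 40 min. Between FU at 40 min and rrp6 at 100 min, which share no library, 279 features were higher and 12 lower in both, against 167 and 0.757, and between FU at 100 min and rrp6 at 40 min 135 and 7, against 108 and 1.34. With median of ratios the overlap was 4 at 40 min and 96 at 100 min. The overlap at 40 min was 8 without wild type replicate 1, 1205 without FU replicate 1, and 3 without FU replicate 2 or either rrp6 library. At 100 min it was 27 and 25 without wild type replicate 1 or 2, 32 and 35 without FU replicate 1 or 2, and 90 and 82 without rrp6 replicate 1 or 2.

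Between 40 and 100 min in wild type, genes that rose include some of methionine and sugar metabolism and of mitosis, and genes that fell include some histone genes. MET17 rose by 5.01 ± 0.24 (adjusted p = 3.50e-05), SAM2 by 4.98 ± 0.54 (adjusted p = 0.00298), SAM1 (YLR180W, chromosome 12, 515262 to 516410) by 4.30 ± 0.21 (adjusted p = 3.50e-05), MXR1 (YER042W, chromosome 5, 234937 to 235491), a methionine sulfoxide reductase, by 4.06 ± 0.47 (adjusted p = 0.00371) and MET6 (YER091C, chromosome 5, 339864 to 342167), the methionine synthase, by 3.87 ± 0.38 (adjusted p = 0.00168). Of the sulfur and methionine genes, 15 of 30 rose (22 over the list alone). The sulfur and methionine list had adjusted p = 2.83e-31, or 0.104 with estimated correlation. Of the glycolysis genes, 12 of 16 rose (13 over the list alone). The glycolysis list had adjusted p = 2.26e-20, or 0.104 with estimated correlation. Of the G2/M genes, 8 of 24 rose (15 over the list alone). The G2/M list had adjusted p = 3.63e-14, or 0.104 with estimated correlation. Of the M/G1 genes, 10 of 30 rose (18 over the list alone). The M/G1 list had adjusted p = 1.85e-18, or 0.104 with estimated correlation. Of the histone genes, 3 of 10 fell (9 over the list alone). The histone list had adjusted p = 8.22e-08, or 0.320 with estimated correlation. Of the G1/S genes, 3 of 41 fell (16 over the list alone). The G1/S list had adjusted p = 3.42e-10, or 0.320 with estimated correlation. TOS6 (YNL300W, chromosome 14, 65744 to 66052) fell by 3.09 ± 0.29 (adjusted p = 0.00147), HSP30 (YCR021C, chromosome 3, 156109 to 157107), a heat shock protein of the plasma membrane, fell by 3.13 ± 0.53 (adjusted p = 0.0196) and RCK1 (YGL158W, chromosome 7, 207033 to 208571), a protein kinase, fell by 3.17 ± 0.63 (adjusted p = 0.0359). YAL037C-A (chromosome 1, 73426 to 73518) had a density of 0.173 ± 0.0598 at 40 min and 0 reads in both libraries at 100 min (adjusted p = 0.00195). ANS1 was at -3.08 ± 0.63 (adjusted p = 0.0394, and 0.0503 with median of ratios). In all, 150 features rose and 122 fell. The count was 48 without the 100 min replicate 1 and 26 without the 100 min replicate 2; ANS1, HSP30 and RCK1 lost their call without some library.

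With FU, some DNA damage genes rose over the same interval. HUG1 rose by 4.58 ± 0.28 (adjusted p = 0.000460), RNR4 by 3.38 ± 0.40 (adjusted p = 0.00665), the iron gene FIT2 (YOR382W, chromosome 15, 1059531 to 1059992) by 3.85 ± 0.31 (adjusted p = 0.00158), CLB1 (YGR108W, chromosome 7, 703636 to 705051), a mitotic cyclin, by 3.22 ± 0.38 (adjusted p = 0.00665) and MET17 by 2.75 ± 0.24 (adjusted p = 0.00193). Of the DNA damage genes, 4 of 26 rose (4 over the list alone). The DNA damage list had adjusted p = 0.000138, or 0.423 with estimated correlation. ANS1 (YHR126C, chromosome 8, 359702 to 360181) fell by 4.08 ± 0.63 (adjusted p = 0.0165), TOS6 fell by 4.02 ± 0.29 (adjusted p = 0.000964), EGT2 fell by 3.35 ± 0.45 (adjusted p = 0.0105), HSP30 fell by 3.17 ± 0.53 (adjusted p = 0.0192) and YMR244W fell by 3.09 ± 0.52 (adjusted p = 0.0201). Of the M/G1 genes, 0 of 30 rose and 9 fell (1 and 15 over the list alone). The M/G1 list had adjusted p = 1.84e-05, or 0.423 with estimated correlation. Of the ribosome biogenesis genes, 23 of 104 fell (50 over the list alone). The ribosome biogenesis list had adjusted p = 3.07e-15, or 0.423 with estimated correlation. In all, 158 features rose and 303 fell with FU. The count moved widely with the library left out, and 4 of the 10 named calls held without any 1 library.

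In rrp6, FET3 rose by 3.13 ± 0.31 (adjusted p = 0.00515) between the times, and AIM20 by 2.94 ± 0.33 (adjusted p = 0.00539). The non-coding feature XUT1143 (chromosome 5, 294542 to 294744), which overlaps CUT558, rose by 3.09 ± 0.50 (adjusted p = 0.0206). SUT355 rose by 2.88 ± 0.35 (adjusted p = 0.00762) and MUT623, which overlaps XUT0328, rose by 2.85 ± 0.30 (adjusted p = 0.00515). POL30 (YBR088C, chromosome 2, 424990 to 425766), the replication clamp PCNA, fell by 2.33 ± 0.22 (adjusted p = 0.00515), TOS4 (YLR183C, chromosome 12, 520543 to 522012) fell by 2.23 ± 0.30 (adjusted p = 0.0115) and CDC21 (YOR074C, chromosome 15, 466675 to 467589), the thymidylate synthase that FU inhibits, fell by 2.15 ± 0.42 (adjusted p = 0.0375). YAL037C-A fell by 2.54 ± 0.39 (adjusted p = 0.0184), and ANS1 was at -3.34 ± 0.63 (adjusted p = 0.0344, and 0.0627 with median of ratios). Of the G1/S genes, 15 of 41 fell (36 over the list alone). The G1/S list had adjusted p = 5.30e-26, or 0.237 with estimated correlation. Of the amino acid synthesis genes, 10 of 39 rose and 0 fell (22 and 1 over the list alone). The amino acid list had adjusted p = 6.15e-13, or 0.248 with estimated correlation. In all, 124 features rose and 90 fell. With only the rrp6 libraries 2320 were called, and all 10 named calls held. Without 1 library, which leaves 1 in a group, each of the 10 ended at least once. The median log2 SD was 0.13 and 0.12 in rrp6 (40 and 100 min), 0.35 and 0.16 in wild type, and 0.36 and 0.20 with FU.

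The interactions ask whether the effects of FU and of rrp6 differ between the times. The FU effect was larger at 100 min for HUG1, by 3.36 ± 0.39 (adjusted p = 0.0226), and was lower for the M/G1 genes EGT2, by -6.21 ± 0.64 (adjusted p = 0.0192), and PCL9, by -4.44 ± 0.48 (adjusted p = 0.0192). Of the M/G1 genes, 6 of 30 fell (23 over the list alone) in this sense. The M/G1 list had adjusted p = 2.24e-31, or 0.119 with estimated correlation. For the effect of rrp6 the difference was -4.09 ± 0.35 for MET17 (adjusted p = 0.00399) and -3.65 ± 0.30 for SAM1 (adjusted p = 0.00399), and of the sulfur and methionine genes 0 of 30 rose and 5 fell (1 and 13 over the list alone) in this sense. The sulfur and methionine list had adjusted p = 6.99e-16, or 0.245 with estimated correlation. The FU interaction had 1 higher and 11 lower features and the rrp6 interaction 2 and 7. The FU count was 0 by limma without either wild type or either FU library of 100 min, 32 without FU replicate 1 and 6 without wild type replicate 2 at 40 min (843 at an unadjusted p under 0.05 with all libraries, and 10 by limma-voom). The rrp6 count was 3 and 2 without wild type replicate 1 or 2 at 100 min, 4 without either rrp6 library of 40 min and 3 without either of 100 min.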

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

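The tests of low abundance and of exosome activity were chosen before their results were seen and the others after. The tests in rrp6 alone were chosen once the FU part of the test over 4 comparisons had not held, and that of each gene against its snoRNA after both were seen. The conditions on pairings of libraries and on correlation between genes were added after the values were seen.

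These results stand out because an interaction test found that an effect differs between 40 and 100 min. The FU effect differed for 12 features: HUG1 by 3.36, and AMN1 by -3.92, PCL9 by -4.44, EGT2 by -6.21, DSE3 by -4.33, AIM44 by -3.72, SAM1 by -2.48, YLR049C by -2.85, DSE4 by -5.52, NIS1 by -2.66, BUD9 by -2.56 and SUT1290 by -2.94 (log2, 100 min minus 40 min). The rrp6 effect differed for 9: IZH3 by 1.59, and ARN2 by -3.33, SAM1 by -3.65, MET17 by -4.09, MUP1 by -2.53, MMP1 by -3.48, MHT1 by -3.09 and PHO12 by -3.14. The fitted value of MUT729, 3.90, rests on wild-type libraries listed at 0 at 100 min. With median of ratios DSE4 (adjusted p = 0.0621) and IZH3 (adjusted p = 0.0567) lose the call.

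CUTs were higher with FU, more than genes, though with estimated correlation the list is not called (adjusted p = 0.802 at 40 min) and at 100 min not at all (adjusted p = 0.186). Median of ratios scaling cannot test the scaling as the cause of the difference from genes at 40 min. Its 1 factor per library moves CUTs and genes alike, except through the pseudocount. On that scaling the difference was 0.54, from 0.44. It fell in none of the 4 pairings of libraries (smallest change 0.031). It was 0.44 and 0.64 in replicates 1 and 2, and -0.35 and 1.47 in the others. For the CUT calls scaling stays open: 0 of 71 were called by limma. The CUT median fell from 0.81 to 0.55 and the spread grew (median standard error 0.40 before and 0.44 after). The lower folds alone left 19 higher, and the larger spread alone 29. CUT medians of 0.81 and 0.52 exceeded matched gene lists (0.37 and 0.41, percentile 100). This omits spread between libraries, so low abundance stays open. At 100 min, where all genes had 0.30, part of the excess goes with abundance. Lower exosome activity with FU may contribute, as FU and rrp6 effects with no shared library correlate across CUTs (Spearman, lower value 0.370), but genes correlate too (0.434 and 0.201) and the RRP6 value with FU was 0.64 ± 0.21 and 0.53 ± 0.21. The replicate 2 libraries of 40 min stay open. Libraries of the same number deviate together (r = 0.778 between wild type and FU), and CUTs lay 0.35 and 0.56 above genes in replicates 1 and 2. Without both replicate 2 libraries FU at 40 min gave 361 calls, 95 of them CUTs higher. That speaks against a need for them, but rests on 1 library per group with the spread of other groups, and the other pairings gave -0.52 and 1.44.

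Of 30 same-strand genes within 1000 nt past a snoRNA, 20 and 19 rose and 5 and 1 fell in rrp6 (40 and 100 min). Over all 4 comparisons chance stays open (lowest percentile 73.11). So does transcription running on past the snoRNA (smallest difference from 71 other neighbours 0.15, FU at 100 min). Reads of the snoRNA may play a part (gene minus snoRNA -0.50). In rrp6 alone the set medians of 1.36 and 1.02 lay above matched lists (0.41 and 0.39, percentile 100), but chance stays open. Camera gave p = 0.249 and 0.465 against all features, and against genes p = 0.000496 and 0.00178, or 0.116 and 0.151 with estimated correlation. In rrp6 transcription running on may explain the rise (smaller difference 0.89, lower bound 0.34). Where the snoRNA rose by less than 0.5, 9 genes had medians of 1.97 and 1.13 (intervals -0.73 to 3.98 and -0.42 to 3.54). Of these, 5 and 6 were called higher and 2 and 1 lower, which alone does not decide on snoRNA reads. Of the 30, 4 rose more than their snoRNA at both times (YCR015C, HEM4, USE1 and IMO32, adjusted over the 30, named afterwards). For them this speaks against reads of the annotated snoRNA only.

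M/G1 genes were lower with FU at 100 min. The scaling is excluded as the cause for their calls, since 13 of 13 stay called with median of ratios; without 1 library 6 or 7 of the 13 stay called. An earlier point of the cell cycle may explain the fall and stays open, since the lists point both ways: histone and G1/S medians lay at least 0.21 above the median gene, while against wild type at 40 min histones were at -1.09 and G2/M genes at 0.49.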

How the results depend on the processing

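Limma-voom, median of ratios with the block, leaving out both 40 min libraries of 1 replicate number, and leaving out FU or rrp6 libraries for the overlap were chosen after seeing the data. DESeq2 was not run. At a depth of 20102931 reads or more per library, the spread between 2 replicates limits small changes. Of simulated 2-fold changes with FU at 40 min 18% were recovered, with independent noise and the same spread in all groups. Of 363 named calls on 235 features, those with the same direction and call numbered 362 without a filter, 352 without a variance trend, 359 with the replicate block, 356 and 330 with the smaller and larger pseudocount, 339 with limma-voom, 311 with median of ratios and block, 280 with median of ratios, 248 with only the compared groups, 232 with quantile normalization and 153 with snoRNA scaling. With a stricter filter 345 did and 1 was weaker, and with genes only 268 did and 8 were weaker. Libraries of the same replicate number gave correlations of 0.23 to 0.78 over the 6 pairs of wild-type and FU groups, and -0.09 to 0.27 over the 9 pairs with rrp6. This hints at pairing of wild-type and FU libraries, from the data and not from the labels, with 2 libraries per group. Apart from genes only, which tests fewer features, smaller sets of libraries, and CUTs with median of ratios, the cause was not tested for the values below.

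Counts that moved are given in the order of the comparisons. With the smaller pseudocount they were 416 (FU at 100 min) and 134 (time in rrp6), and with the larger 16 and 164 (FU at 40 and 100 min), 911 (time in rrp6) and 43 (rrp6 by time). With median of ratios they were 5 and 119 (FU), 20 lists (FU at 40 min), and overlaps of 4 and 96. With snoRNA scaling they were 1 and 30 (FU), 3065 and 3675 (rrp6), 1448 and 2420 (FU against rrp6), 38, 7 and 7 (time), and 2 and 0 by limma (interactions; 877 for rrp6 at an unadjusted p under 0.05, and 8 by limma-voom). With quantile normalization they were 4 and 110 (FU), 4451 (rrp6 at 100 min), 727 (time in rrp6) and 0 by limma (FU by time; 843 at an unadjusted p under 0.05, and 10 by limma-voom). With genes only they were 48 (FU at 40 min), 1914 and 2054 (rrp6), 446 and 948 (FU against rrp6) and 14 lists (rrp6 at 100 min), and general stress in rrp6 at 100 min turned upward (adjusted p = 0.770). With the block they were 924 (167 CUTs higher) and 536 (FU), 480, 903 and 391 (time), and overlaps of 866 and 458. With only the compared groups they were 0 and 38 (FU), 2243 (FU against rrp6 at 40 min), 0, 0 and 2320 (time), and 0 and 4 (interactions). For the 0 values, from limma, all groups together gave 3230 (FU at 40 min), 1972 and 2771 (time in wild type and with FU) and 843 (FU by time) at an unadjusted p under 0.05, and limma-voom 79, 232, 438 and 10. Limma-voom gave 79 (FU at 40 min). Median of ratios with block gave 52 (FU at 40 min, 37 higher and 15 lower, with 16 CUTs higher and 17 of the 38 named calls), 635 (time in wild type), 354 (time in rrp6) and 16 (rrp6 by time). Without both replicate 1 libraries FU at 40 min gave 1528, and without both replicate 2 libraries 361, within 1.5 times the count. With an estimated correlation 1 list is called for FU at 100 min and 0 in each other comparison.

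Leaving out 1 library, where the lone sample is assumed to vary like the other groups, gave 6 to 1340 and 34 to 45 (FU), 5039 to 6638 and 5242 to 5630 (rrp6), 2240 to 4036 and 3205 to 3992 (FU against rrp6), 26 to 402, 13 to 1012 and 0 to 27 (time), 0 to 32 and 2 to 8 (interactions), and overlaps of 3 to 1205 and 25 to 90. Of named calls so tested 1187 held and 393 did not.

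Directions reversed with snoRNA scaling in rrp6 at 40 min for SSE1 (-0.084), PDR3 (-0.0018) and NOP1 (-0.14). With quantile normalization they reversed at 40 min for SIC1 (-0.086), YOX1 (-0.24), STE2 (-0.18), ASG7 (-0.53), MF(ALPHA)2 (-0.38), MET3 (-0.22), SUL1 (-0.37), FLR1 (-0.36) and PDR3 (-0.49). At 100 min they did for NRM1 (-0.44), ASG7 (-0.10), SAG1 (-0.65), GPA1 (-0.38), HO (-0.24), PUS5 (-0.53), RRN9 (-0.011), FCY22 (-0.26), DDI3 (-0.14), ALD3 (-0.067), HSP26 (-0.035), RPT1 (-0.14), FLR1 (-0.21), PDR1 (-0.043) and BCD1 (-0.068).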

Other observations

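Lists of the sexual cycle held many called genes in rrp6, though camera over all features called none. Of the pheromone genes, 19 of 27 rose (20 over the list alone) at 40 min and 21 of 27 rose (21 over the list alone) at 100 min. The pheromone median was 0.61 and 0.83 (adjusted p = 0.312 and 0.195). Of the meiosis genes, 18 of 28 rose (18 over the list alone) at 40 min and 17 of 28 rose (17 over the list alone) at 100 min. The meiosis median was 0.50 (but -0.056 with quantile normalization) and 0.72 (adjusted p = 0.395 and 0.243). Of the a-specific genes, 4 of 7 rose (5 over the list alone) at 40 min and 6 of 7 rose (6 over the list alone) at 100 min. The a-specific median was 0.52 (but -0.089 with quantile normalization) and 1.31 (adjusted p = 0.565 and 0.216). Of the haploid-specific genes, 9 of 11 rose (9 over the list alone) at 40 min and 6 of 11 rose and 1 fell (6 and 1 over the list alone) at 100 min. The haploid-specific median was 0.59 and 0.19 (but -0.54 with quantile normalization) (adjusted p = 0.501 and 0.441). Tested against genes alone, which leaves the many raised non-coding features out, the adjusted p was 0.00158 and 0.000376 for pheromone genes, 0.00245 and 0.000652 for meiosis genes, 0.0811 and 0.0143 for a-specific genes, and 0.0326 and 0.509 for haploid-specific genes. With estimated correlation none was called there (lowest adjusted p = 0.225, pheromone genes at 100 min). Of the mitochondrial genome features, 0 of 10 passed the limma test, with 1 higher and 0 lower at an unadjusted p under 0.05, 1 called by limma-voom, and 0 rose over the list alone at 40 min and 2 of 10 rose (0 over the list alone) at 100 min. The mitochondrial median was -0.25 (but 0.55 with quantile normalization) and -0.016 (but 0.88 with quantile normalization) (adjusted p = 0.00994 and 0.195, or 0.658 and 0.756 with estimated correlation). All mitochondrial DNA held 15.3% ± 0.690 and 11.4% ± 0.731 of gene reads in rrp6, and 9.02% ± 2.84 and 6.25% ± 1.08 in wild type (± SD, n = 2).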
